A study of Escherichia coli str. K-12 substr. MG1655 with 6 samples.

How the data were processed

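RNA was sequenced in 6 libraries from Escherichia coli K-12 MG1655, a standard laboratory strain, grown overnight in LB medium at 37 °C. Per the labels' protocols, 3 libraries came from untreated cells and 3 from cells exposed for 20 min to ciprofloxacin at 2 µg per mL. Ciprofloxacin is a fluoroquinolone antibiotic that traps DNA gyrase and topoisomerase IV on DNA. Ribosomal RNA was depleted before library making and the libraries were run on an Illumina instrument, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

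The deposited table holds 1 FPKM value (fragments scaled by gene length and by mapped fragments) per gene and library, as the authors computed it. Bowtie2 2.2.3, HTSeq 0.6.1, DESeq 1.18.0, Picard 1.96, SAMtools 0.1.18 and GATK are named in the submitters' processing notes, without role or order. The genome build, the annotation, the strand setting and the filters are not given in the sources used here. Reads of a gene and of an antisense partner can therefore not be told apart. The deposited FPKM values carry no further scaling between samples that could be seen: the column totals ran from 1222440 to 1760810.

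Of 4581 features, 4486 matched a locus tag of the RefSeq table of assembly ASM584v2, which was used for names, gene order and gene length. Its coordinates were not printed, since no build is named for the values. The 95 unmatched features comprised 51 and 33 features under 2 kinds of provisional ID and 11 locus tags absent from that table. The matched features were 4176 protein-coding genes, 138 pseudogenes, 86 tRNAs, 63 other non-coding RNAs, 22 rRNAs and 1 of another kind. At most 0.220 FPKM of rRNA was left in any library, so no check of rRNA depletion could be drawn from these values.

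Low FPKM values multiplied by gene length fell on repeated steps, and the step gave the mapped reads of each library. Between 93.9% and 97.2% of the values of up to 20 reads came out whole within 0.1 read. By this route the untreated libraries held 4365272, 2949576 and 3945772 mapped reads, and the ciprofloxacin libraries 3397467, 3171707 and 3353070. Pairs of replicates differed far beyond sampling noise, with a chi-square per degree of freedom of 87.6 to 451 over genes, so no pair looked like 1 library deposited more than once. This does not show separate cultures.

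Values were analysed as log2(FPKM + 1), and a fold change on this scale understates the change of weakly expressed genes. Genes with a mean under 1 FPKM over the 6 libraries were left out, which kept 4293. The groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, all 6 libraries and no further covariate. P-values were adjusted by the Benjamini-Hochberg method and called under a threshold of 0.05. Every adjusted p given for a gene is limma's moderated test, two-sided, with n = 3 per group except on omission of a library, where 1 group has n = 2 (both groups without both replicate 1 libraries).

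Gene lists were written from textbook knowledge before the data were examined, as were the comparison, the threshold and the rule for the genes named. There were 29 lists, of which 770 of 771 entries matched a feature, and 28 had the 5 or more tested members needed for a test. They covered the SOS (LexA) regulon, other DNA repair, chromosome replication, topoisomerases, nucleoid-associated proteins, ribonucleotide reductases, cell division, ribosomal proteins, aminoacyl-tRNA synthetases, flagella and chemotaxis, heat shock, oxidative stress, iron uptake and iron-sulfur cluster assembly. The others were general stress (RpoS), acid resistance, envelope stress, cold shock, multidrug efflux and porins, toxin-antitoxin systems, the cryptic prophages e14 and Rac, the tricarboxylic acid cycle, the aerobic respiratory chain, ATP synthase, anaerobic respiration and fermentation, purine and pyrimidine synthesis, amino acid synthesis, curli and type 1 fimbriae, and structural RNAs. Each was tested with camera, which compares the list's members with all other tested genes, at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists. Camera with an estimated correlation and fry, a rotation test of the list itself, were run beside it. The genes named were the 5 with the largest rise and the 5 with the largest fall among called genes with a mean of at least 10 FPKM and no overlap between groups, the 2 members with the largest absolute change in each list (4 for the SOS regulon), and recA, lexA, sulA, gyrA, gyrB, parC, parE and topA. The rule gave 72 genes. Other genes are named as examples from the lists, chosen after their values were seen.

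The titles number the samples 2 and 3 in each group, and the first sample of each group, whose title carries no number, was taken as 1. Same-numbered libraries deviated together from their group means, with correlations across genes of 0.372, 0.352 and 0.170 for numbers 1, 2 and 3, and each library correlated best with its own number. Deviations within a group sum to 0, so the other pairings are not separate evidence. A fit with the replicate number as a block was therefore set beside the unblocked one where it changed a call or moved a count by over 1.5 times. The pairing rests on these correlations and on the titles, since no label describes a shared culture or day.

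The scripts were tested on simulated data for 4212 genes with 3 libraries per group. Of 50 genes each given a log2 change of 1, 2, 3 or 4, the share called was 0%, 26%, 72% and 90%. Among 4012 unchanged genes 8 were called, and 1 of 200 random lists had a camera p under the threshold. The simulated genes varied independently of each other, whereas the correlation estimated within the SOS list, for example, was 0.508. The simulation therefore does not show camera's error rate for correlated genes. The alternatives tried were other pseudocounts, filters, scalings, variance settings, sample weights and the replicate block, the omission of each library, and voom on the recovered reads. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.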

Results

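Transcript levels in E. coli K-12 MG1655 were compared between 3 untreated libraries and 3 libraries from cells held for 20 min with ciprofloxacin at 2 µg per mL, a dose the study calls high. The values were FPKM per gene. Mapped reads per library, recovered from the steps of the low values, ran from 2949576 to 4365272 in untreated and from 3171707 to 3397467 in treated cells. A named gene had a median of 83 to 96 reads in the untreated libraries and of 27, 51 and 51.1 in treated replicates 1, 2 and 3. On log2(FPKM + 1) values the first principal component held 57.6% of the variance and separated the groups. The second held 26.0% and placed both replicate 1 libraries (33.1 untreated and 65.2 treated) apart from the other 4, which lay between -39.6 and -9.02.

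The comparison asked which genes respond to a high dose of ciprofloxacin. The SOS regulon, the genes that the LexA repressor controls and that DNA damage switches on, held the largest rise of any gene. Transcripts of recA, which encodes the recombinase that senses damaged DNA, made up 0.0787% to 0.178% of reads in untreated libraries and 5.15% to 6.19% in treated ones. The gyrase genes gyrA and gyrB rose as well. Falls were called in 42 of 78 tested genes of amino acid synthesis, 25 of 51 of flagella and chemotaxis and 14 of 35 of iron uptake, and none of these lists passed with an estimated correlation (adjusted p = 0.9998). In all, 1212 of 4293 tested genes changed at an adjusted p under 0.05, of which 273 rose and 939 fell, and all 1212 moved by at least 1 on the log2 scale. The median log2 change over all tested genes was -0.67, so the balance of rises and falls depended on the scaling: 787 genes rose and 453 fell with each library centred on its median, 613 and 609 after quantile normalization, and 647 and 549 with voom and median-ratio size factors. Without untreated replicate 2 there were 578 calls (158 rose, 420 fell), without untreated replicate 3 there were 563 (131 and 432), and without ciprofloxacin replicate 3 there were 733 (133 and 600). Without ciprofloxacin replicate 1 the rises numbered 580, without ciprofloxacin replicate 2 they numbered 165, and without both replicate 1 libraries 1822 genes were called (611 rose, 1211 fell).

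Of the 32 tested SOS members, 19 rose, none fell and 13 did not pass the test. The largest rise in the whole data set was that of tisB (b4618), which encodes a small membrane toxin, at 194339 ± 78587 FPKM in treated against 1271 ± 250 in untreated libraries (SD, n = 3 each), a log2 change of 7.20 ± 0.49 (SE, adjusted p = 0.000617). Its coding sequence is very short, so FPKM weights it heavily, and istR, which lies beside it, encodes an antisense RNA of the same locus. The inhibitor of RecA filaments, recX (b2698), rose from 11.1 ± 3.06 to 1067 ± 421 FPKM, and recA (b2699) itself from 1093 ± 510 to 52275 ± 4991, which is 50.9-fold on the log2(FPKM + 1) scale (log2 change 5.67 ± 0.47, adjusted p = 0.000617). The damage-induced gene yebG (b1848) rose by a log2 change of 5.19 and sulA (b0958), the inhibitor of cell division, by 4.31 (19.8-fold, adjusted p = 0.00214). Excision repair genes uvrA (4.48) and uvrB (4.25) and the genes umuD (4.16), polB (3.59) and dinB (3.10) of the SOS polymerases rose too. The repressor gene lexA (b4043), which represses itself, was at 1583 ± 929 FPKM against 926 ± 471, and its log2 change of 0.72 ± 0.56 did not pass (adjusted p = 0.365), though it did with each library centred on its median (1.61, adjusted p = 0.0294). The other 12 members that did not pass included yafO (2.31), ybfE (2.03), dinF (1.48), ssb (1.14), ruvA (0.76), uvrD (0.48) and ftsK (0.11).

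Adjusted over the list alone, 20 SOS members rose. The median log2 change of all 32 tested members was 2.42, which is 3.11 above that of the other genes (camera adjusted p = 6.41e-20, adjusted p = 0.9998 with an estimated correlation). The unadjusted camera p with an estimated correlation was 0.0554, and the adjustment gave all 28 tested lists the same 0.9998. In all 3 treated libraries recA, tisB, recX, yebG and sulA lay above every untreated library. With median centring 28 members rose.

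**Figure D1:**
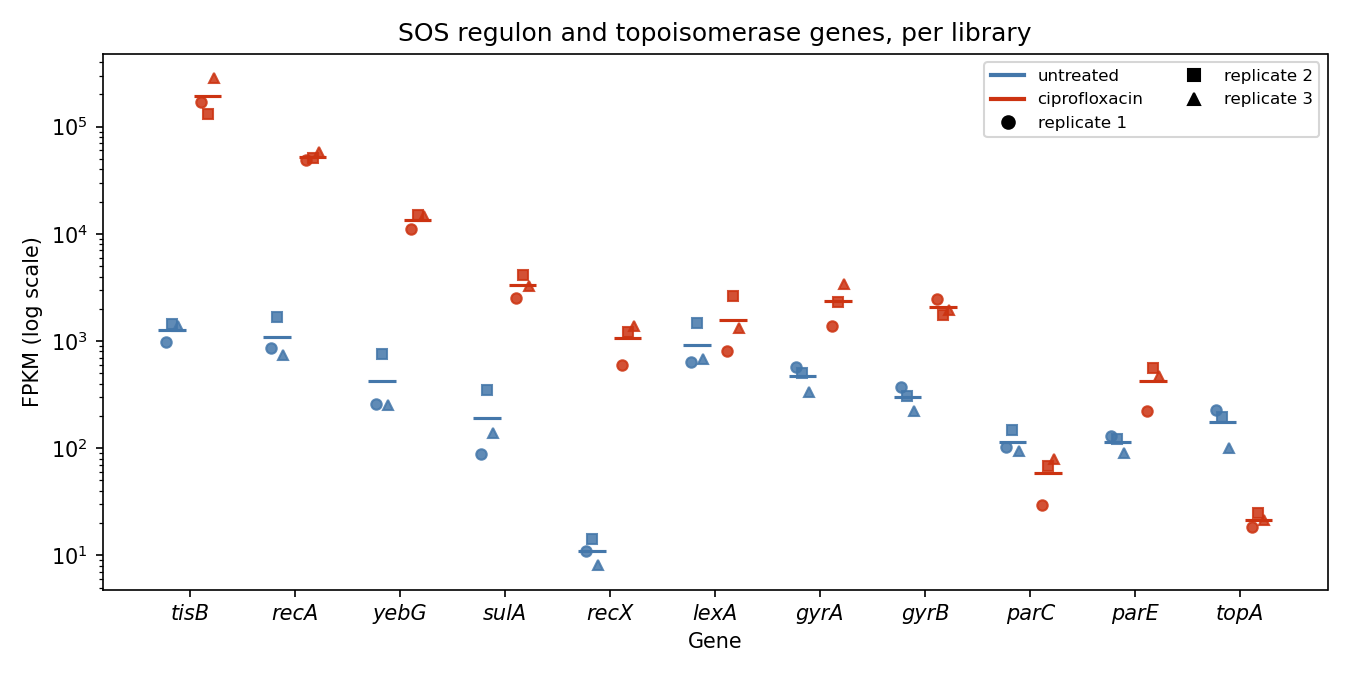
FPKM of SOS and topoisomerase genes in each library on a log axis, with untreated libraries in blue, ciprofloxacin libraries in red, symbols for the replicate number and bars for the group mean (n = 3). Treated recA lay at 48376 FPKM or above and untreated recA at 1678 or below, while lexA and parC overlapped or did not pass the test.

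Ciprofloxacin binds DNA gyrase, which adds negative supercoils, and topoisomerase IV, which separates daughter chromosomes. Both gyrase genes rose: gyrA (b2231) from 468 ± 120 to 2373 ± 1020 FPKM (log2 change 2.28 ± 0.48, adjusted p = 0.0104) and gyrB (b3699) from 302 ± 78.4 to 2062 ± 384 (2.79 ± 0.41, adjusted p = 0.00298). The last of the 4 genes of the operon that dnaA begins is gyrB. Of its neighbours there, dnaA rose by 2.47 and recF, beside gyrB, by 2.65, and whether these rises are separate was not tested. The topoisomerase IV subunit gene parE (b3030) rose by 1.79 ± 0.47 (adjusted p = 0.0240), whereas its partner parC (b3019) changed by -1.03 ± 0.50 and did not pass (adjusted p = 0.155). Topoisomerase I, encoded by topA (b1274) and known to remove negative supercoils, fell from 175 ± 66.2 to 21.5 ± 3.26 FPKM (log2 change -2.89 ± 0.46, adjusted p = 0.00369), and topB fell by 1.90 on the log2 scale. Thus 3 of the 6 topoisomerase members rose, 2 fell and 1 did not pass, and adjusted over the list alone 3 rose and 2 fell. As a list they did not stand apart (camera adjusted p = 0.339), with a median of 0.38 and a mean of 0.17. The call for gyrA was lost without untreated replicate 3 (adjusted p = 0.0509), and that for parE on omission of any single library except ciprofloxacin replicate 1, with adjusted p from 0.0531 to 0.0997. With median centring 1 of the 6 members fell, and 1 rise was called without untreated replicate 3, and 1 fall without untreated replicate 1, untreated replicate 3 or ciprofloxacin replicate 2.

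Outside the SOS regulon the largest rise of a named gene was that of htrL (b3618), from 21.9 ± 6.40 to 1581 ± 690 FPKM (log2 change 6.04 ± 0.49, adjusted p = 0.000617). A pair of features with provisional IDs also rose: Novel00015 by 7.14 ± 0.54 and Novel00007 by 6.24 ± 0.66. The largest falls were in genes of the maltose transporter, malF (b4033, log2 change -6.58 ± 1.17, adjusted p = 0.00558) and malG (b4032, -5.99 ± 1.05). They were followed by the tryptophan transporter gene tnaB (b3709, -5.57 ± 1.40), the glycine cleavage gene gcvP (b2903, -5.53 ± 0.46, adjusted p = 0.000617) and the methionine sulfoxide reductase gene msrC (b1832, -5.13 ± 0.41). The spread of malF and tnaB was wide, with 528 ± 422 and 2574 ± 768 FPKM in untreated cells against 3.64 ± 4.99 and 274 ± 452 in treated cells. Untreated malF was at 44.8 FPKM in replicate 1 and at 713 and 825 in replicates 2 and 3. Treated tnaB was at 796 FPKM in replicate 1 and at 16.2 and 9.56 in replicates 2 and 3. Without both replicate 1 libraries the log2 change of tnaB was -7.80 (adjusted p = 0.00139). The call for tnaB was lost with median centring (adjusted p = 0.0726) and with voom and median-ratio size factors (adjusted p = 0.0652). It was also lost without untreated replicate 2 (adjusted p = 0.0570), untreated replicate 3 (adjusted p = 0.0619), ciprofloxacin replicate 2 (adjusted p = 0.0646) or ciprofloxacin replicate 3 (adjusted p = 0.0584).

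Ribosomal protein genes stood above the other genes. Of 54 tested, 9 rose, none fell and 45 did not pass the test, and adjusted over the list alone 4 rose. The examples with the largest change were rpmH (b3703), from 1188 ± 530 to 15993 ± 8397 FPKM (log2 change 3.71 ± 0.60, adjusted p = 0.00369), and rpmG (b3636, 2.95 ± 0.92, adjusted p = 0.0422), with rpsL at 2.43 and rpsG at 2.31. The median log2 change was 0.80, which is 1.51 above the other genes (camera adjusted p = 5.27e-11, adjusted p = 0.9998 with an estimated correlation). With median centring 39 members rose, without ciprofloxacin replicate 1 there were 20, and without both replicate 1 libraries 26. Without untreated replicate 2 there were 4, and 3 were called on omission of untreated replicate 3, ciprofloxacin replicate 2 or ciprofloxacin replicate 3. The call for rpmG was lost on omission of any single library except untreated replicate 1, with adjusted p from 0.0630 to 0.137, and with equal protein-coding totals (adjusted p = 0.0579). Among 23 aminoacyl-tRNA synthetases, which charge tRNAs for translation, none rose, 4 fell and 19 did not pass (camera adjusted p = 0.774). The falls included ileS (b0026, -3.06) and serS (b0893, -2.76), and adjusted over the list alone 4 fell. Of these synthetases 3 rose without ciprofloxacin replicate 1, and with median centring 2 rose and 3 fell.

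Amino acid synthesis was the list with the most falls. Of 78 tested members 42 fell, none rose and 36 did not pass, and adjusted over the list alone 43 fell. The aromatic amino acid synthesis gene aroG (b0754) fell from 284 ± 55.1 to 9.72 ± 2.53 FPKM (log2 change -4.75 ± 0.43, adjusted p = 0.000855), and the histidine gene hisI (b2026) from 91.8 ± 22.7 to 4.10 ± 1.52 (-4.20 ± 0.46). The aromatic genes aroF (0.51) and aroH (-1.04) did not pass. The aspartokinase gene lysC (-3.78) and ilvD (-3.42) of branched-chain synthesis fell as well. The median was -1.93, which is -1.27 relative to other genes (camera adjusted p = 3.49e-06, adjusted p = 0.9998 with an estimated correlation). With median centring 26 members fell and 3 rose.

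Of 51 tested genes of flagella and chemotaxis, 25 fell, none rose and 26 did not pass, cheW (0.28) and trg (0.46) among them, and adjusted over the list alone 30 fell. The rod gene flgB (b1073) and the hook assembly gene flgD (b1075) fell from 84.0 ± 77.7 and 83.6 ± 57.6 FPKM to 1.21 ± 1.48 and 1.90 ± 0.74, with log2 changes of -5.00 ± 0.84 and -4.66 ± 0.61. The master regulator gene flhD fell by 2.37 on the log2 scale. The list median was -1.90, which is -1.24 relative to other genes (camera adjusted p = 4.33e-06, adjusted p = 0.9998 with an estimated correlation). With median centring 15 fell, without untreated replicate 2 there were 12 and without untreated replicate 3 there were 10.

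Of 35 tested iron uptake genes under the Fur repressor, 14 fell, none rose and 21 did not pass, among them fur itself (0.85), and adjusted over the list alone 15 fell. The ferrous iron transporter genes feoB (b3409, -3.06 ± 0.47) and feoA (b3408, -2.61 ± 0.67) led the falls, followed by fecI (-2.60) and tonB (-2.35). The median was -1.14, which is -0.48 relative to other genes (camera adjusted p = 0.0225, adjusted p = 0.9998 with an estimated correlation). The list's call was lost over genes of at least 10 FPKM (adjusted p = 0.506), with such members only (adjusted p = 0.392), with array weights (adjusted p = 0.0566) and without ciprofloxacin replicate 1 (adjusted p = 0.0725). With median centring 2 members fell and 1 rose, and falls numbered 1 on omission of untreated replicate 2 or untreated replicate 3, 6 of ciprofloxacin replicate 2 and 3 of ciprofloxacin replicate 3. The call for feoA was lost without untreated replicate 2 (adjusted p = 0.0891), untreated replicate 3 (adjusted p = 0.0801) or ciprofloxacin replicate 3 (adjusted p = 0.0551), and with voom and median-ratio size factors (adjusted p = 0.0528).

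Of 15 tested members of iron-sulfur cluster assembly 2 rose, 4 fell and 9 did not pass, and adjusted over the list alone 4 rose and 5 fell. In the Isc system hscB (1.99) and iscA (1.76) rose. In the Suf system, which serves under iron or oxidative stress, sufA (b1684) fell from 36.8 ± 8.18 to 8.41 ± 3.11 FPKM (log2 change -2.04 ± 0.48, adjusted p = 0.0156). Another gene of this system, sufS (b1680, -2.15 ± 0.71, adjusted p = 0.0519) passed only in some alternatives, among them the replicate block (adjusted p = 0.0171) and the omission of ciprofloxacin replicate 1 (adjusted p = 0.00800). The median was 0.48, the mean was -0.07 and the camera direction was up (adjusted p = 0.270). With median centring 6 members rose and none fell, and without untreated replicate 2 or untreated replicate 3 none was called in either direction. Without ciprofloxacin replicate 2 there were 1 rise and no fall, without ciprofloxacin replicate 3 there were no rise and 1 fall, and without untreated replicate 1 there were 4 rises and 1 fall. The list itself passed without untreated replicate 1 (adjusted p = 0.0334), and the call for sufA was lost with median centring (adjusted p = 0.105) and without untreated replicate 2 (adjusted p = 0.0826), untreated replicate 3 (adjusted p = 0.0536) or ciprofloxacin replicate 2 (adjusted p = 0.0528).

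Toxin-antitoxin genes, which pair a growth-inhibiting toxin with its antidote, included 7 members that rose, 1 that fell and 18 that did not pass, of 26 tested. With counts adjusted over the list alone, 7 rose and 1 fell. The SOS members tisB, symE, yafN and yafO (2.31, not passed) are in this list too. The gene symE (b4347) rose from 8.34 ± 6.43 to 135 ± 43.6 FPKM (log2 change 4.11 ± 0.65, adjusted p = 0.00355), and the antisense RNA symR overlaps it. Outside the SOS regulon yoeB (2.46), yefM (2.43), relE (2.15) and relB (2.09) rose, and rnlA fell by 3.99 on the log2 scale. The median was 0.70, which is 1.38 above other genes (camera adjusted p = 0.000284, adjusted p = 0.9998 with an estimated correlation). With median centring 14 members rose, without untreated replicate 3 there were 4, and with the replicate block 2 fell.

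Genes of the cryptic prophages e14 and Rac, remnants of phage genomes in the chromosome, were mixed. Of 37 tested, 5 rose, 1 fell and 31 did not pass, and adjusted over the list alone 5 rose and none fell. The e14 genes lit (b1139, 3.54 ± 0.55, adjusted p = 0.00336) and ymfE (b1138, 3.49 ± 0.63) rose, as did ynaK (3.16) of Rac, and ymfI of e14 fell by 1.67. The median was 0.16, which is 0.84 above other genes (camera adjusted p = 0.0137, adjusted p = 0.9998 with an estimated correlation). With the replicate block 8 rose and 2 fell, and with median centring 12 rose and none fell. Without untreated replicate 2 there were 2 rises, and without untreated replicate 3 or ciprofloxacin replicate 3 there were 3, with no fall in any of these. Without ciprofloxacin replicate 1 there were 8 rises and 3 falls.

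DNA repair outside the SOS regulon did not move as a list. Of 25 members 2 rose, 4 fell and 19 did not pass (camera adjusted p = 0.999). The uracil glycosylase gene ung (b2580, -3.66 ± 0.46, adjusted p = 0.00191) and the transcription-repair coupling gene mfd (b1114, -3.32 ± 0.43) fell. In chromosome replication 3 of 22 members rose, 5 fell and 14 did not pass (camera adjusted p = 0.892). The repair polymerase gene polA (b3863) fell from 248 ± 48.8 to 16.0 ± 1.83 FPKM (-3.86 ± 0.41) and the initiator-binding gene diaA (b3149) fell by 3.21 on the log2 scale, while the initiator gene dnaA rose by 2.47. Of 22 cell division genes, 6 fell, none rose and 16 did not pass (camera adjusted p = 0.270). The 6 were minC, minD and minE, which place the division site, and mukB, mukE and mukF, the condensin that organizes the chromosome, with minD (b1175, -3.77 ± 0.39) and mukB (b0924, -3.48 ± 0.41) the most changed. Of 11 nucleoid-associated proteins 2 rose, among them fis (b3261, 2.90 ± 0.72, adjusted p = 0.0193), 3 fell, among them cbpA (b1000, -3.08 ± 0.50), and 6 did not pass (camera adjusted p = 0.774). None of 8 genes listed for ribonucleotide reductases, enzymes that make deoxyribonucleotides, passed under limma (camera adjusted p = 0.517). The regulator gene nrdR (b0413) was at 1.24 ± 0.45 (adjusted p = 0.0709) and nrdF (b2676) at -1.07 ± 0.68.

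Adjusted over the list alone, 2 repair genes rose and 4 fell, 3 replication genes rose and 6 fell, 6 division genes fell, 2 nucleoid genes rose and 4 fell, and no reductase gene passed. With median centring 6 repair genes rose and 2 fell, 7 replication genes rose, 4 division genes rose, and 3 nucleoid genes rose and 1 fell. In the reductase list 1 gene then rose, the regulator gene nrdR (adjusted p = 0.0146). Without ciprofloxacin replicate 1 there were rises of 6 repair, 5 replication, 3 division and 3 nucleoid genes and of 2 genes of the reductase list. Omission of any other single library gave 0 or 1 rise in repair, 0 to 2 in replication and 0 to 2 among nucleoid genes. Without untreated replicate 2 or untreated replicate 3 there were falls of 2 repair genes, 3 replication genes and 1 nucleoid gene, without untreated replicate 1 of 3 replication genes, and without ciprofloxacin replicate 3 of 1 nucleoid gene. The call for fis was lost without untreated replicate 3 (adjusted p = 0.0765), ciprofloxacin replicate 2 (adjusted p = 0.0622) or ciprofloxacin replicate 3 (adjusted p = 0.0645).

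None of the lists for stress responses other than SOS passed as a list. Of 24 genes under the general stress factor RpoS, 5 rose, 9 fell and 10 did not pass (camera adjusted p = 0.774). The lipoprotein gene osmB (b1283) rose 9.69-fold on the log2(FPKM + 1) scale (log2 change 3.28 ± 0.60, adjusted p = 0.00608) and osmY by 2.28, while the outer membrane lipocalin gene blc (b4149) fell by 3.86 on the log2 scale. Of 20 heat shock genes 1 rose, 2 fell and 17 did not pass (camera adjusted p = 0.517), the falls being htpX (b1829, -2.58 ± 0.58) and clpP (b0437, -1.44 ± 0.37). Of 21 genes of oxidative stress 1 fell, the glucose-6-phosphate dehydrogenase gene zwf (b1852, -1.56 ± 0.40, adjusted p = 0.0201), and 20 did not pass (camera adjusted p = 0.999), among them ahpF (b0606, -1.52 ± 0.59), and 2 fell with the replicate block, 4 with array weights and 7 with equal protein-coding totals. Of 26 envelope stress genes 11 fell, none rose and 15 did not pass (camera adjusted p = 0.206), including the sigma factor regulators rseA (b2572, -2.63 ± 0.57) and rseB (b2571, -2.51 ± 0.52), and with the replicate block 2 rose and 14 fell. Of 13 cold shock genes 4 fell and 9 did not pass (camera adjusted p = 0.329), with cspA (b3556) at -3.58 ± 0.95 and cspB (b1557) at -3.43 ± 0.69. None of 19 acid resistance genes passed under limma (camera adjusted p = 0.270), with hdeD (b3511) at -2.52 ± 0.83 and gadE (b3512) at 1.98 ± 0.81, but with the replicate block 2 rose and 3 fell, gadE (adjusted p = 0.0195) and hdeD (adjusted p = 0.00864) among them.

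Adjusted over the list alone, 5 RpoS genes rose and 11 fell, 2 heat shock genes fell, 1 envelope stress gene rose and 14 fell, 4 cold shock genes fell, and no oxidative stress or acid resistance gene passed. With median centring 4 RpoS genes fell, 2 envelope stress genes rose and 1 fell, 4 heat shock genes rose and none fell, 1 oxidative stress gene rose and none fell, and 4 acid resistance genes rose. That scaling ended the calls for htpX (adjusted p = 0.101), clpP (adjusted p = 0.353), zwf (adjusted p = 0.249), rseA (adjusted p = 0.0881) and rseB (adjusted p = 0.0775). The call for cspA was lost without any 1 of the untreated replicates, with adjusted p from 0.0560 to 0.0721. Falls in envelope stress numbered 3 without untreated replicate 2, 5 without untreated replicate 3 and 7 without untreated replicate 1 or ciprofloxacin replicate 3, and the list passed without untreated replicate 3 (adjusted p = 0.0485) or ciprofloxacin replicate 1 (adjusted p = 0.0428). The acid resistance list passed without untreated replicate 1 (adjusted p = 0.0154), with 1 gene that rose, gadE (adjusted p = 0.0309), and hdeD passed without untreated replicate 2 (adjusted p = 0.0352) or ciprofloxacin replicate 1 (adjusted p = 0.0314). RpoS genes that rose numbered 5 without ciprofloxacin replicate 1 and 1 to 3 without any other library, and those that fell numbered 4 without untreated replicate 2 or untreated replicate 3 and 5 without ciprofloxacin replicate 3. Heat shock falls numbered 7 without ciprofloxacin replicate 1 and 0 to 2 without any other, with no rise there, and cold shock falls 2 without any 1 of the untreated replicates. No oxidative stress gene fell without untreated replicate 2, untreated replicate 3 or ciprofloxacin replicate 3, where zwf had an adjusted p from 0.0683 to 0.0993. The calls for htpX and clpP were lost without untreated replicate 2 (adjusted p = 0.0580 and 0.0837), and that for clpP also without untreated replicate 1, untreated replicate 3 or ciprofloxacin replicate 3 (adjusted p from 0.0620 to 0.0857).

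Efflux and porin genes, which set how much of a drug enters or leaves the cell, held 1 member that rose, mdtK (1.43), 6 that fell and 20 that did not pass, of 27 tested (camera adjusted p = 0.774). The efflux genes emrA (b2685, -3.04 ± 0.60, adjusted p = 0.00797), emrB (-2.40) and acrB (-1.80) fell. The maltoporin gene lamB (b4036) stood at 42.2 ± 50.7 FPKM in treated and 2817 ± 2796 in untreated libraries (-4.88 ± 2.54) and did not pass (adjusted p = 0.179), but it did with the replicate block (adjusted p = 0.00720). With the block 2 members rose and 10 fell, with median centring 4 rose and 1 fell, and adjusted over the list alone 1 rose and 6 fell. Without ciprofloxacin replicate 1 there were 5 rises and without any other single library none, and falls numbered 1 without untreated replicate 2 and 3 without untreated replicate 3 or ciprofloxacin replicate 3. The call for lamB was also gained without untreated replicate 1 (adjusted p = 0.0161).

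In the aerobic respiratory chain the genes that fell lay in the distal part of 1 operon. Of 24 tested members 7 fell, none rose and 17 did not pass, and all 7 were genes of NADH dehydrogenase I, nuoH to nuoN. Along the nuo operon the log2 change went from 0.27 ± 0.54 at nuoA, the first gene, to -4.76 ± 0.75 at nuoM (b2277, adjusted p = 0.00355) and -4.18 ± 0.55 at nuoN (b2276, adjusted p = 0.00222). The nuoM level was 365 ± 168 FPKM in untreated and 17.1 ± 18.7 in treated libraries, and nuoN was at 489 ± 217 and 27.1 ± 16.5. The list did not pass (camera adjusted p = 0.270), with a median of -0.67, like that of all genes, and a mean of -1.28. The number that fell was also 7 when adjusted over the list alone. The list passed without untreated replicate 3 (adjusted p = 0.0471).

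**Figure D2:**
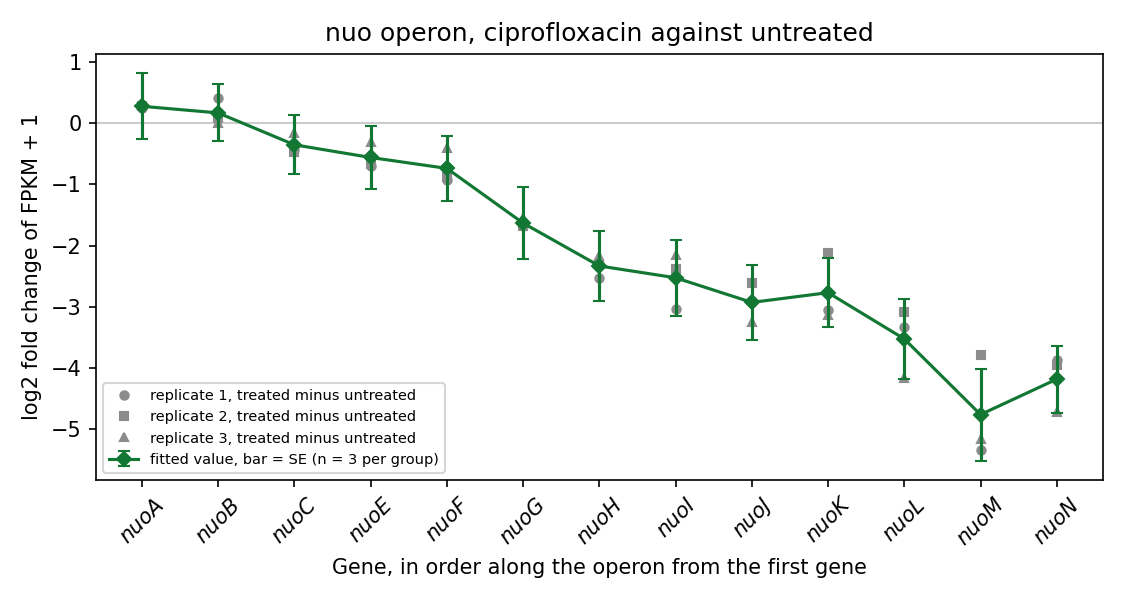
Log2 fold change of FPKM + 1 (ciprofloxacin minus untreated) for the 13 genes of the nuo operon in their order from the promoter, with the fitted value and its SE (n = 3 per group) in green and the 3 same-numbered pairs in grey. The change went from 0.27 at nuoA to -4.18 at nuoN.

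Of 9 ATP synthase genes 3 fell and 6 did not pass (camera adjusted p = 0.798), with atpD (b3732) at -2.05 ± 0.53 and atpC (b3731) at -1.93 ± 0.56. Of 21 genes of the tricarboxylic acid cycle 4 fell and 17 did not pass (camera adjusted p = 0.999), with fumB (b4122) at -3.56 ± 0.92 and aceA (b4015) at -2.14 ± 0.67. Of 30 genes of anaerobic respiration and fermentation 4 fell and 26 did not pass (camera adjusted p = 0.774). These were the dimethyl sulfoxide reductase genes dmsA, dmsB (b0895, -4.36 ± 0.60) and dmsC (b0896, -4.48 ± 0.68, adjusted p = 0.00317) and the pyruvate formate-lyase gene pflB, and with the replicate block 10 fell. When adjusted over the list alone, 3 ATP synthase genes, 2 cycle genes and 4 anaerobic genes fell. With median centring no ATP synthase gene fell and 1 rose, no cycle gene fell, 1 anaerobic gene rose, and the calls for atpD (adjusted p = 0.172), atpC (adjusted p = 0.227), fumB (adjusted p = 0.0793) and aceA (adjusted p = 0.122) ended. On omission of untreated replicate 2, untreated replicate 3 or ciprofloxacin replicate 3 no ATP synthase gene passed, and of ciprofloxacin replicate 2 only 1. On any single omission falls of cycle genes numbered 1 or 2, and aceA then had an adjusted p from 0.0521 to 0.145. The call for fumB was lost on omission of untreated replicate 1, untreated replicate 3, ciprofloxacin replicate 1 or ciprofloxacin replicate 2 (adjusted p from 0.0503 to 0.0797). The camera direction was down for ATP synthase, the cycle and the aminoacyl-tRNA synthetases, while their medians lay 0.27, 0.50 and 0.09 above other genes.

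Of 26 purine and pyrimidine synthesis genes 1 rose, 5 fell and 20 did not pass (camera adjusted p = 0.999). The carbamoyl phosphate synthetase gene carB (b0033, -2.58 ± 0.62) and purN (b2500, -2.35 ± 0.52) fell and purA rose by 1.67. Of 21 curli and fimbria genes the recombinase gene fimE (b4313) rose, from 4.01 ± 1.71 to 64.3 ± 68.5 FPKM (3.08 ± 0.86, adjusted p = 0.0286), none fell and 20 did not pass (camera adjusted p = 0.194). Its partner fimB (b4312, 1.87 ± 0.85, adjusted p = 0.133) passed with the replicate block (adjusted p = 0.0359), where 2 members of the list rose and 1 fell, and without ciprofloxacin replicate 1 (adjusted p = 0.0132), where 2 rose. Adjusted over the list alone 1 purine or pyrimidine gene rose and 4 fell, and no curli or fimbria gene passed. With median centring 5 purine or pyrimidine genes rose and 3 fell, and 5 curli or fimbria genes rose. Purine and pyrimidine rises numbered 4 without ciprofloxacin replicate 1 and 0 without any other library, and falls 8 without ciprofloxacin replicate 1, 2 without untreated replicate 3 and 0 without untreated replicate 2. The calls for carB (adjusted p = 0.0638) and purN (adjusted p = 0.0585) were lost without untreated replicate 2, and that for carB without untreated replicate 3 (adjusted p = 0.0534). The call for fimE was lost on omission of any single library except ciprofloxacin replicate 1, with adjusted p from 0.0609 to 0.0834. Of 26 structural RNA entries only ssrS (b2911, 1.14 ± 0.84, adjusted p = 0.336) and ffs (b0455, 0.50 ± 1.04) were tested, and neither passed, though ssrS did without untreated replicate 1 (adjusted p = 0.0469).

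**Figure D3:**
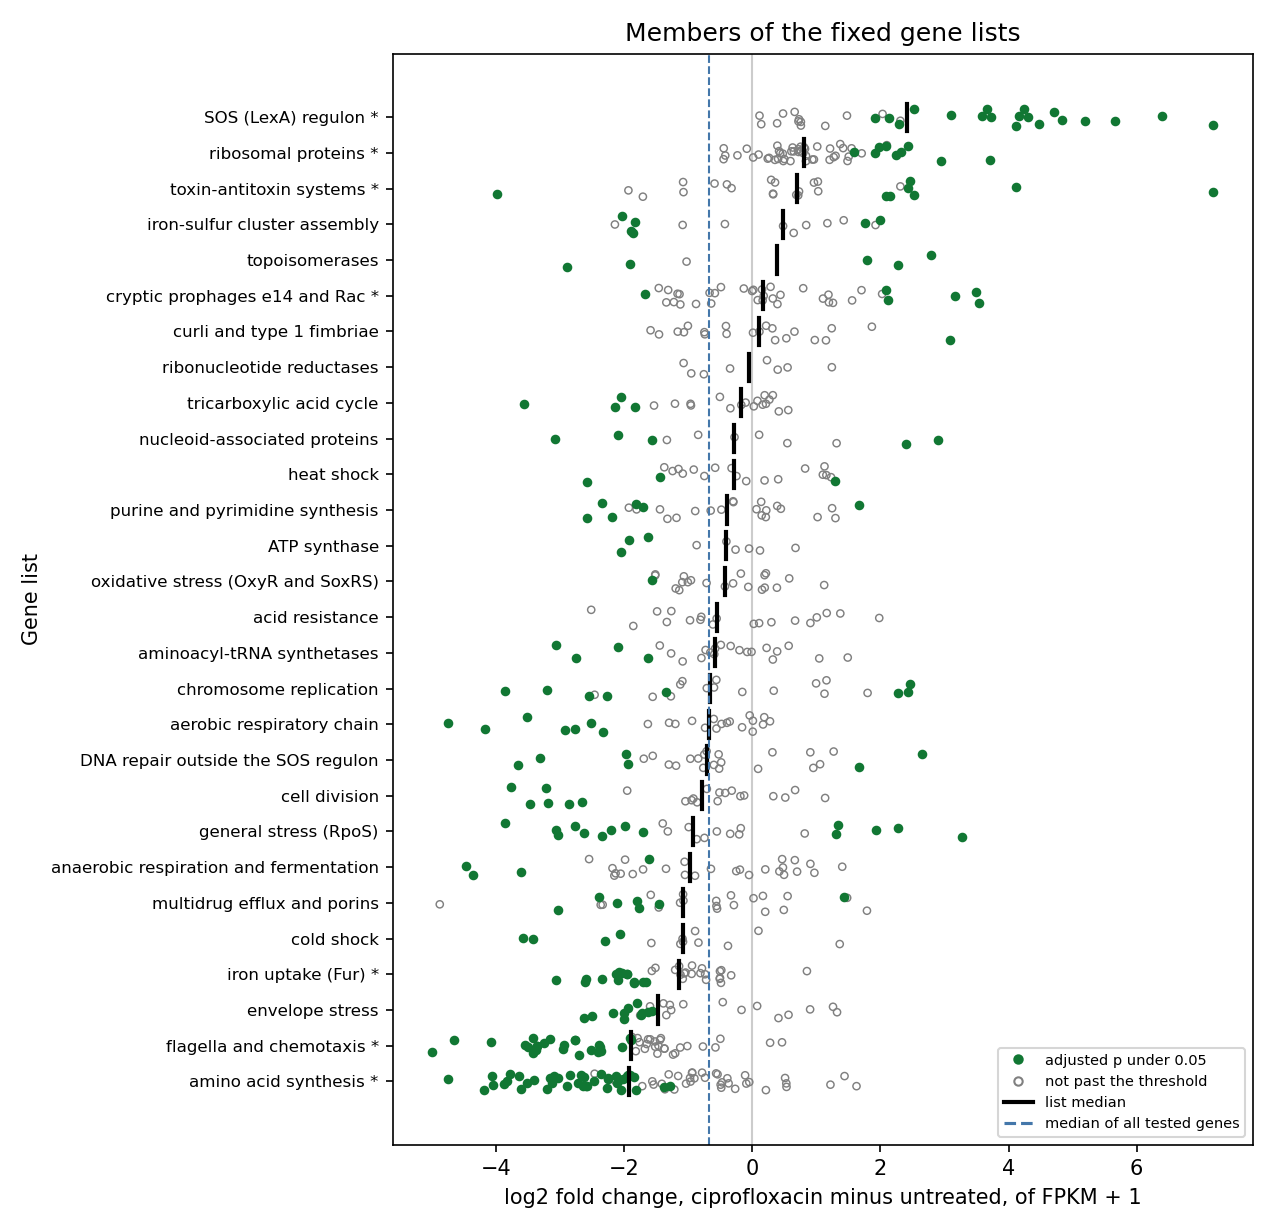
Log2 fold change of FPKM + 1 (ciprofloxacin minus untreated, n = 3 per group) for every tested member of the 28 tested lists, filled where the adjusted p was under 0.05, with the list median as a black bar and the median of all tested genes (-0.67) as a dashed line. Lists with a star passed the camera test, from the SOS regulon with a median of 2.42 to amino acid synthesis with -1.93, and with an estimated correlation none of the 7 passed.

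Longer genes fell more than shorter ones. Across 4019 protein-coding genes the log2 change and gene length had a Spearman rho of -0.165, and genes are not independent replicates. In 4 equal bins of genes from short to long, with median lengths of 348, 699, 1020 and 1557 bp, the median log2 change was -0.29, -0.75, -0.90 and -0.93. Within libraries the rho of level with length was -0.119 ± 0.014 in treated and -0.0360 ± 0.0064 in untreated cells (SD, n = 3 each), with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. The same-numbered pairs gave -0.130, -0.169 and -0.139. Gene order from the replication origin had a rho of -0.0259 with the log2 change, and within libraries -0.111 ± 0.021 against -0.104 ± 0.024 (exact permutation p = 0.8). These were the 2 gene properties tested, and adjusted over both the p-values were 0.2 and 0.8.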

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

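Voom on the recovered reads, the replicate block with median centring and the omission of both replicate 1 libraries were chosen after the data were seen. The total of 1212 called genes became 2053 with array weights (674 rose), 1822 without both replicate 1 libraries (611 rose), 1635 with the replicate block (1208 of them shared with the 1212) and 1637 with equal protein-coding totals. With median centring 787 rose and 453 fell, with quantile normalization 613 and 609, with voom and median-ratio size factors 647 and 549, and with the replicate block and median centring 932 and 545. These scalings took the median log2 change of all genes from -0.67 to 0.22, -0.09, 0.00 and 0.22. Leaving out single libraries gave 563 to 1602 calls, with 131 to 580 rises and 420 to 1022 falls. The lowest total was without untreated replicate 3, and totals were also under 800 without untreated replicate 2 (578) or ciprofloxacin replicate 3 (733).

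Of the 28 lists 7 passed, 7 to 9 on omission of single libraries, 0 with an estimated correlation and 4 with fry, which tests another question. Among the 7, the SOS regulon (fry adjusted p = 0.0248) and amino acid synthesis (0.0239) passed with fry. Ribosomal proteins (0.185), flagella and chemotaxis (0.0623), iron uptake (0.0623), toxin-antitoxin systems (0.173) and the prophages (0.574) did not. The SOS regulon lay 3.11 above other genes (2.94 to 3.52 on omission of single libraries), lost its call with the estimated correlation (adjusted p = 0.9998) and kept it in the other alternatives run. Over all lists and alternatives 646 values kept their side of the threshold, 16 lost the call and 10 gained it. A value without a call in either setting was counted as kept even where its direction turned. Heat shock, for example, was up with camera and down with fry. For the 72 named genes the numbers were 1360, 98 and 45, and no called direction turned. The number of rises or falls moved by over 1.5 times in 13 of the 28 lists with equal protein-coding totals, 20 with quantile normalization, 22 with array weights and 25 with median centring. With equal protein-coding totals 9 genes each of other DNA repair, replication, and purine and pyrimidine synthesis fell, 8 aminoacyl-tRNA synthetases, 5 toxin-antitoxin genes, 5 prophage genes and 4 heat shock genes. Beside the changes printed with the results, the replicate block changed no other call of a list or a named gene. Envelope stress, cold shock and the aerobic chain passed with quantile normalization (adjusted p = 0.0480, 0.0480 and 0.0456), and envelope stress and anaerobic respiration passed with fry.

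The rho of log2 change with gene length was -0.140 with quantile normalization and -0.174 to -0.154 on omission of single libraries, and that with gene order from the origin -0.0424 to -0.0118. Except where an alternative uses fewer samples or genes, the cause of these changes was not tested. GC content was not examined, for want of a sequence, and the count models planned for a table of raw counts were not run. In simulation with 3 libraries per group a log2 change of 1 was called in 0% and of 2 in 26% of genes, and depth was not varied there.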

Other observations

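The tests of ciprofloxacin replicate 1, of the length trend over genes of at least 10 FPKM and of unannotated features were chosen after their results were seen, as was the sign-flip test over operons, while the others were written before. Features with provisional IDs rose more often than named genes: 13 of 32 features of 1 kind of ID and 3 of 20 of the other rose, against 257 of 4241 named genes (6.06%). With median centring the numbers were 19, 5 and 763. The odds ratio was 6.88 (95% interval 3.52 to 12.9, Fisher's exact p = 5.99e-08), and neighbouring features are not independent. What these IDs were called from is not given in the sources used here, and features called from these same libraries would be selected ones, so the test leaves the cause open.

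Of 44 immediate neighbours of SOS genes 6 rose, among them yebF (4.60) beside yebG, rapA (3.67) beside polB, mcrB (2.60) beside symE and yobI (4.21) beside ruvA, which did not pass itself. Another 8 fell, among them yjbR (-3.55) beside uvrA and ybhK (-3.50) beside uvrB, all named after their values were seen. Over all 4293 tested genes 273 rose and 939 fell, so falls were no more frequent among the neighbours. The neighbour counts themselves were not tested. The hypothesis that transcription runs on from SOS genes was tested with the neighbours' median log2 change, -0.36, which lay at percentile 95.7 of 10000 random gene sets matched on level. That met the bound of 95 set beforehand by a narrow margin, and the median lay inside the central 95% range of those sets (-1.33 to -0.30), which was no part of that bound. The neighbours were taken on both sides of each SOS gene and without regard to strand. Genes that such transcription would not reach were thus included, so this test cannot decide the hypothesis.

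More genes fell than rose on the deposited scale, with a median log2 change of -0.67. A difference in depth is argued against, since with every library thinned to the smallest total the median was -0.68 (SD 0.00668 over 10 thinnings). FPKM is scaled by the library total before and after thinning, so only effects of depth on low values could have shown here. With totals counted outside the 100 genes with the most reads the median was -0.46 (-0.64 to -0.28 over the 3 same-numbered pairs), so a few abundant genes could account for part of the shift, and the pairs' SD of 0.181 leaves open whether for more. A fall of most transcripts per cell stays an untested alternative, since the values hold no external standard.

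Ciprofloxacin replicate 1 stood apart from the other treated libraries, with an array weight of 0.170 and tnaA as its most abundant gene by reads, as in the untreated libraries. Mixed-in RNA of untreated cells was examined with untreated replicate 1 only. There tnaA, at 10.1% of reads, lay above the 9.56% of ciprofloxacin replicate 1, whereas untreated replicates 2 and 3 lay below, at 2.79% and 6.20%. A share of 94.6% of untreated replicate 1 would be needed to give the tnaA level. That share would leave the 19 SOS members that rose at a median of 0.0823 of their level in the other treated libraries, where 0.523 was observed (quartiles 0.379 to 0.775). These members were called with this library in the fit, which favours a high ratio. The figure of 94.6% rests on tnaA alone, and tnaB, at 796 FPKM here and 1701 in untreated replicate 1, would need a smaller share. No smaller share was tested against the SOS members. Yet gcvP and msrC stood at 6.25 and 5.32 FPKM here, against at least 401 and 180 in every untreated library. These falls argue against a share as large as tnaB would need, though both genes too were called with this library in the fit. A swap of labels is argued against by 0 untreated libraries with recA above the lowest treated one (1678 against 48376 FPKM). Its deviations correlated with those of untreated replicate 1 at 0.372, and of the 6 ways to pair the libraries the titles' numbers gave the highest mean correlation, 0.298 against 0.181 for the next, a share of 0.167. With so few ways a culture or library day shared by same-numbered libraries stays open, as does which of them it was.

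The fall of longer genes did not rest on the short ribosomal protein genes, since rho was -0.148 without them (-0.152 to -0.120 over the pairs), nor on values near the floor, since it was -0.171 over genes of at least 10 FPKM. For a loss of transcripts with distance from the promoter, the mean rho of log2 change with gene position was -0.213 over 32 operons with 209 genes, fixed before their values were seen (two-sided permutation p = 0.00977 over 100000 permutations; -0.104, -0.229 and -0.257 in the 3 pairs), which met every bound set beforehand, though without the nuo operon the mean was -0.188, short of the bound of -0.2. Genes within an operon are not independent, however, and with each operon as 1 unit a two-sided sign-flip test, added after the result was seen, gave p = 0.0980 (SD of rho 0.707, below 0 in 20 operons and above 0 in 12, such as 0.95 in flgB to flgJ). Within libraries the mean rho of level with position was -0.104 ± 0.0821 in treated and 0.0356 ± 0.0476 in untreated cells (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Such a loss therefore stays open, and 1 value per gene would not tell early stops, decay of distal RNA and library making apart.

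The 6 libraries can be split into 3 and 3 in 10 ways, and only 1, the real one, called 1212 genes in limma. The highest of the other splits called 0, with 14 to 293 genes at an unadjusted p under 0.05 against 1765, and with median centring the highest called 1. With 10 splits a share under 0.05 cannot be reached. In every other split both groups held treated and untreated libraries, so the difference between treatments widened the spread within groups. Few calls were therefore likely in advance, and those splits do not show how many genes chance alone would call. Of the other splits, 3 also part all 3 same-numbered pairs, and these had 14, 16 and 91 genes at an unadjusted p under 0.05.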
